A study of Mus musculus with 2 samples.

How the data were processed

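The data are 2 RNA-seq libraries of mouse MDSCs, 1 from Mettl3 floxed mice without Cre and 1 from mice that also carried LysM-cre, grouped by the genotype in the labels. The series' design text speaks of biological replicates, but each genotype had 1 sample here. Per the labels, cells came from MC38-bearing mice and were co-cultured with MC38 cells for 24 h. One label field of the LysM-cre sample names MC39 in place of MC38, and the difference is left as it stands. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, second strands were marked with dUTP and removed, and paired ends were read on an Illumina NovaSeq. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2 were used with build mm10. Their roles and settings are not given in the sources used here.

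One table of the whole series was used. It holds, per the file headers, a count and an FPKM value per gene row and library, both made by the authors. The deposited count values are whole numbers, not normalized, and how reads were assigned to rows, including multi-mapping reads and strand, is not given in the sources used here. The deposited FPKM values were scaled by the authors for depth and gene length. An FPKM of 0.0001 stood where the count was 0 and was read as 0. The FPKM and count ratios differed by no more than 0.06 on the log2 scale in all 14019 rows with counts above 50 in both libraries. The 8 columns of 4 libraries that no label describes were not used in any step. No comparison of the authors' own was used here. Of the gene identifiers, 55141 were found in GENCODE M21 on the same build, and 94.2% of these had the same start and end. Coordinates are those of the deposited table.

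Total counts were 59506878 in the floxed control library and 59393864 in the library labelled LysM-cre, with TMM factors of 1.00058 and 0.999419 (edgeR 4.0.16, R 4.3.3). Genes with a mean of 1 FPKM or more were kept (12526). The log2 ratio was computed as log2 of the FPKM + 1 in the library labelled LysM-cre over FPKM + 1 in the control, which understates differences of low genes. Genes were counted at 2-fold or more by this fixed rule of size, since 1 library per genotype allows no test. Beside it, the ratio of CPM (counts scaled to the total of the library) is given with an exact 95% (Clopper-Pearson) interval. Paired reads and PCR copies are not independent molecules, so these intervals cover counting error only and are too narrow for anything else. At this depth the interval of Mettl3, on 1413 and 1333 counts, was 0.876 to 1.02.

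A total of 35 gene lists (717 different symbols) was written before the data were examined, covering m6A genes, MDSC functions, signalling, metabolism, stress and the cell types a bead isolation could carry over. Of the symbols, 699 were matched directly, 16 by an older symbol and 2 not at all. For each list with at least 5 genes kept, the median log2 ratio was ranked among 10000 random lists of the same size, matched in 20 bins of mean expression. A list below the 2.5th or above the 97.5th percentile was said to lie outside the random range. The genes named are Mettl3, the 15 with the highest and 15 with the lowest log2 ratio among genes with a mean of 5 FPKM or more and a symbol (without predicted Gm and Rik genes, immunoglobulin and T cell receptor segments and pseudogenes named -ps), up to 4 members of each list with the largest absolute ratio, and any member of the m6A, JAK-STAT3 and suppressive effector lists. The members of the eosinophil list that are listed without values or below the minimum were named after their values were seen. So were Tox4, Lyz2, Pagr1b, Evi2a, Evi2b, the immunoglobulin and sex-linked genes and the repeat-derived row in the closing section. Values of some list members are not reported here.

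Overlap of rows was computed from the table's coordinates and strand, and the log2 ratio was repeated with counts summed over overlapping rows. Rows with near-identical copies, and antisense partners, cannot be told apart with certainty because the handling of strand and multi-mapping reads is unknown. Alternatives were other pseudocounts, TPM, median-ratio and TMM scaling, other minimums and thresholds, subsets of genes, other random lists and the mean in place of the median. The procedure was tested on simulated data of these libraries with 200 changed genes and a gene noise of 10% (coefficient of variation). Of genes made 3-fold higher 94% were called at 2-fold, of genes made 3-fold lower 62%, of genes changed 1.5-fold 0%, and of unchanged genes 0.0243%. Lists of 20 genes shifted by 0.2 on the log2 scale lay outside the random range in 99% of cases and unshifted lists in 4%. The noise was assumed and independent between genes, and no reads were shared between rows. These rates therefore check the procedure and are not error rates in the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The counts of Rps27 and Rps27rt were also summed as a pair, a sum chosen after the results were seen.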

Results

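Gene expression was measured by poly(A)-selected RNA sequencing in myeloid-derived suppressor cells (MDSCs), immature and activated neutrophil-like and monocyte-like cells known for restraining T cells in tumours. The cells were isolated with magnetic beads from C57BL/6 mice bearing tumours of MC38, a mouse colon adenocarcinoma line, and were then kept in co-culture with MC38 cells for 24 h. The mice were 8 weeks old. One genotype carried floxed Mettl3 alleles without Cre (1 library), and the other carried the same alleles together with LysM-cre, a Cre recombinase placed at the lysozyme 2 locus that is active in myeloid cells (1 library). Mettl3 encodes the catalytic subunit of the nuclear complex that writes N6-methyladenosine (m6A) on messenger RNA. The deposited table held 59506878 counts for the floxed control library and 59393864 counts for the library labelled LysM-cre, over 55401 gene rows. With 1 library per genotype there was no replicate check on any difference, and no p-value is given. Where a ratio of depth-scaled counts is given, its exact 95% interval covers counting error only, so it compares these libraries and not the genotypes.

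The first comparison asked whether the targeted gene was lower in the library labelled LysM-cre. It was not lower beyond counting error at the level of the whole gene. Mettl3 (ENSMUSG00000022160, chromosome 14, 52294841 to 52305128 on the minus strand, mm10) stood at 4.16 FPKM (fragments per kilobase, scaled to the depth of the library) in the floxed control library and at 3.92 FPKM in the library labelled LysM-cre. These values rested on 1413 and 1333 counts, a ratio of depth-scaled counts (CPM) of 0.945 (95% interval 0.876 to 1.02). On the log2(FPKM + 1) scale the difference was −0.07. Mettl14, the partner of Mettl3 in the methyltransferase complex, stood at 1.91 and 1.71 FPKM (CPM ratio 0.893, 95% interval 0.813 to 0.981). Wtap, which anchors the complex, stood at 14.2 in each library. Tox4, on the plus strand (52279146 to 52296401), overlaps the lower end of the Mettl3 coordinates and stood at 14.2 and 13.7 FPKM, and how strand was handled in the counts is unknown, so a part of Tox4 reads in the Mettl3 value is not excluded. How much of the gene-level value came from the floxed exons is not in the labels either, so the value neither shows nor excludes a deletion of these exons. Directions below are therefore given for "the library labelled LysM-cre".

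The m6A genes as a group lay near the same level in both libraries. Of 24 listed writers, erasers and readers, 21 had a mean of 1 FPKM or more, with 11 higher and 10 lower in the library labelled LysM-cre. Their median log2 ratio was 0.01, at the 54.2th percentile of 10000 random lists of the same size and expression level. The largest differences in the group were small. Mettl5, a methyltransferase for ribosomal RNA, stood at 2.67 FPKM in the control and 3.17 in the library labelled LysM-cre. The m6A reader Ythdf2 stood at 9.33 and 8.35 FPKM (CPM ratio 0.895, 95% interval 0.848 to 0.945). The erasers Fto (2.93 and 2.83 FPKM) and Alkbh5 (15.1 and 14.8 FPKM) differed less.

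The second comparison asked which genes differed most between the libraries. Most genes lay at nearly the same level in both libraries. Among 12526 genes with a mean of 1 FPKM or more, 11715 (93.5%) differed by less than 1.5-fold in FPKM + 1. This scale understates differences of low genes. The median log2 ratio was 0.00. At least 2-fold higher FPKM + 1 in the library labelled LysM-cre was found for 164 genes and at least 2-fold lower for 148. Only 107 of these 312 genes were protein-coding (59 higher and 48 lower, of 10246 kept), while 64 were immunoglobulin genes (30 higher and 34 lower, of 221 kept). The count interval lay wholly beyond 1.5-fold for 106 of the 107 protein-coding genes. These genes were selected by their ratio in the same libraries, so at this depth that outcome was nearly fixed in advance. The counts of genes depended on the pseudocount, with 251 higher and 252 lower at a pseudocount of 0.1 FPKM and 62 higher and 54 lower at 5 FPKM.

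**Figure D1:**
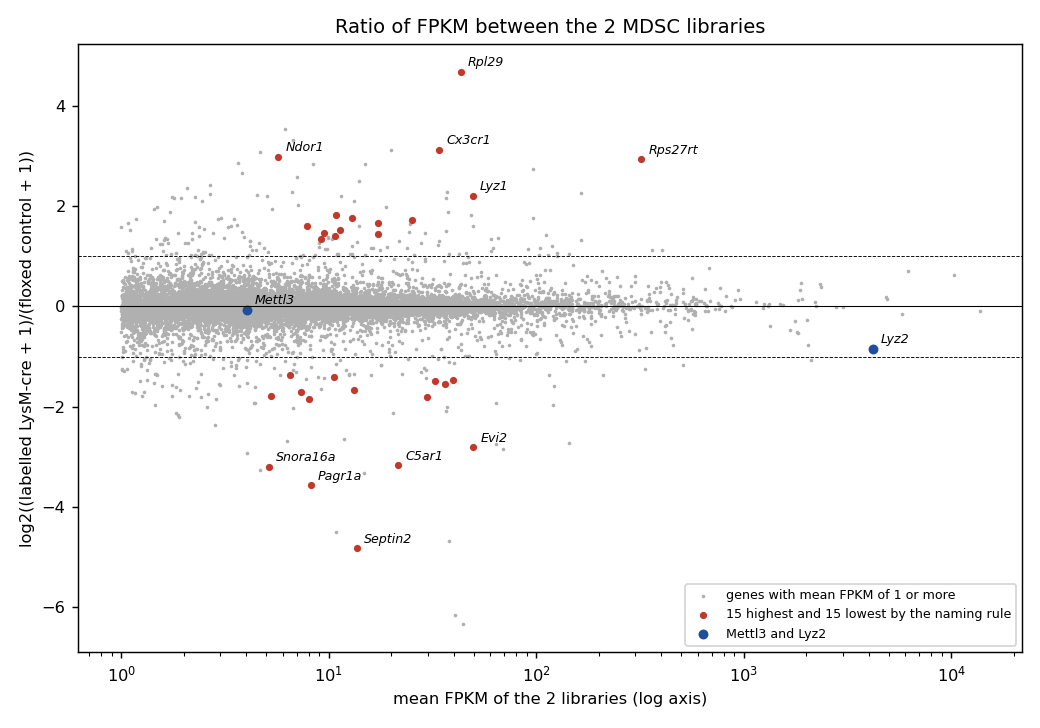
Log2 ratio of FPKM + 1 between the libraries (vertical axis, library labelled LysM-cre over floxed control) against mean FPKM (horizontal log axis) for the 12526 genes with a mean of 1 FPKM or more, with dashed lines at 2-fold. Red points are the 15 highest and 15 lowest genes by the naming rule, and blue points are Mettl3, near 0 at −0.07, and Lyz2 at −0.84.

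Among the 15 named genes with the highest ratios, Cx3cr1, the fractalkine receptor of monocytes (chromosome 9, 119901616 to 120068296), stood at 6.16 FPKM in the control and 61.6 in the library labelled LysM-cre (CPM ratio 9.99, 95% interval 9.52 to 10.5). Its row overlapped 3 other rows on the same strand, and with their counts summed the log2 ratio was 1.67 in place of 3.13. Marco, a scavenger receptor of macrophages, stood at 8.83 and 25.9 FPKM (2.93, 2.73 to 3.13). Ear6, a ribonuclease gene of the eosinophil-associated family, stood at 4.75 and 13.5 FPKM. Lyz1, the lysozyme gene next to Lyz2, stood at 16.9 and 81.9 FPKM (4.83, 4.56 to 5.11). It held 1430 and 6891 counts, against 474780 and 263725 for Lyz2. How multi-mapping reads were handled is unknown, so Lyz2 reads counted at Lyz1 are not excluded and the Lyz1 value is uncertain. Metabolic and signalling genes in this group were Scd2, a fatty acid desaturase (4.24 and 17.5 FPKM), Sgsh, a lysosomal sulfatase (5.32 and 17.2), Osgin1 (4.60 and 14.4), the tyrosine kinase gene Abl1 (CPM ratio 2.95, 95% interval 2.85 to 3.06), the transcriptional repressor gene Zbtb7a (5.35 and 20.5), the nuclear envelope gene Tor1aip1 (11.2 and 39.1) and the ubiquitin-conjugating enzyme gene Ube2g2 (7.68 and 26.7). The ribosomal protein genes Rpl29 (2.32 and 84.2 FPKM) and Rpl21 (3.38 and 12.4) share their description with 2 and 11 pseudogene rows with counts, so these values are uncertain. Rps27rt (73.1 and 565) is a retrotransposed relative of Rps27. Its counts were 1828 and 14088 while those of Rps27 were 45148 and 33163, and the pair together held 46976 and 47251. The Ndor1 entry was 1 of 3 rows with that symbol, whose summed counts were 3093 and 3794.

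Among the 15 named genes with the lowest ratios, C5ar1 had the lowest of those with no overlapping row on the same strand. It encodes the receptor for the complement fragment C5a, which recruits and activates myeloid cells. C5ar1 (chromosome 7, 16246743 to 16259540) stood at 39.6 FPKM in the control and 3.52 in the library labelled LysM-cre, on 6807 and 605 counts (CPM ratio 0.0890, 95% interval 0.0818 to 0.0968). Ly6a, which encodes the surface protein Sca-1 and is a member of the monocyte list, stood at 58.9 and 20.8 FPKM (0.352, 0.333 to 0.373). Transport and membrane genes in this group were Slc43a2, an amino acid transporter (20.7 and 5.83 FPKM), Flvcr1, a haem and choline transporter (9.79 and 3.18), Atp6v0c, a subunit of the vacuolar proton pump (54.5 and 17.9), and the tetraspanin gene Tspan14 (48.4 and 16.7). Pygo2, a Wnt pathway cofactor (13.1 and 2.94 FPKM), the phosphatase gene Ctdsp2 (47.0 and 12.7), the zinc finger gene Zfp292 (8.76 and 1.81) and Pcyt1a, an enzyme of phosphatidylcholine synthesis (11.8 and 2.93), were also lower. Atp6v0c and Ctdsp2 each share their description with 1 pseudogene row with counts, so their values are uncertain too. The Septin2 row held 6085 counts in the control and 0 in the library labelled LysM-cre, whereas both Septin2 rows together held 6774 and 6780. With overlapping rows on the same strand summed, the log2 ratio of Snora16a moved from −3.20 to 0.04. That of Mir692-2 moved from −1.41 to 1.38, that of Pagr1a from −3.57 to −1.43 and that of Evi2 from −2.81 to −1.65. Pagr1b, which overlaps Pagr1a, went the other way, with 25 counts in the control and 149 in the library labelled LysM-cre. The rows overlapping Evi2 were nearer to level, with 2360 and 2070 counts for Evi2a and 5218 and 4450 for Evi2b. Most of the summed difference at Evi2 therefore came from its own row.

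The third comparison asked whether groups of genes chosen before the data were examined moved together. Of 33 lists with at least 5 genes kept, 10 lay outside the middle 95% of random lists, 6 higher and 4 lower in the library labelled LysM-cre, against 1.65 if genes were independent. Genes of a pathway are not independent, so the percentiles describe these libraries only. Using the mean of the members in place of the median, 3 lists lay outside, which were the type I interferon, granulocyte precursor and eosinophil lists.

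**Figure D2:**
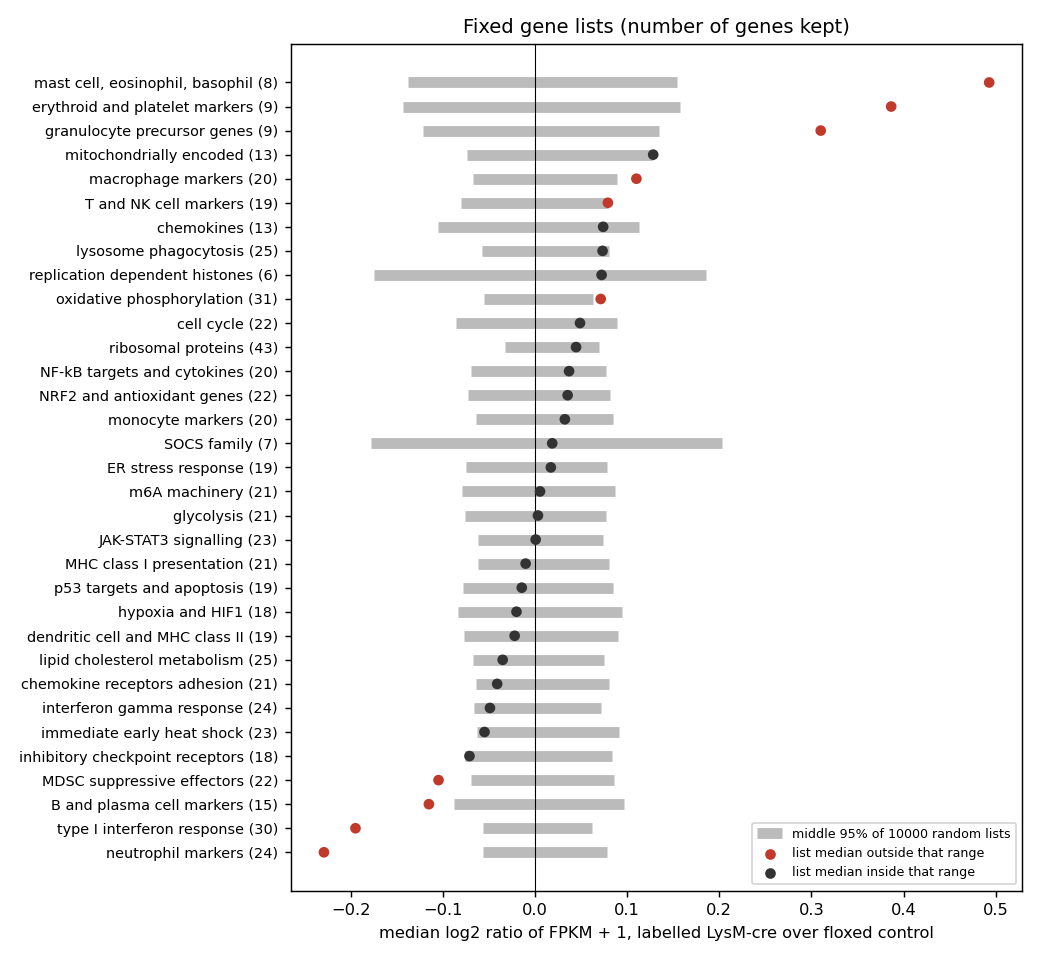
Median log2 ratio of FPKM + 1 (horizontal axis, library labelled LysM-cre over floxed control) for the 33 lists with a percentile, with the number of genes kept in brackets. Grey bars hold the middle 95% of 10000 random lists matched on expression. The neutrophil list lies lowest at −0.23 and the mast cell, eosinophil and basophil list highest at 0.49.

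Neutrophil and suppressive genes were modestly lower in the library labelled LysM-cre. Of 24 neutrophil markers, 18 were lower and 6 higher, with a median log2 ratio of −0.23 (percentile 0.00 for the median and 3.00 for the mean). Ly6g, the surface marker of mouse neutrophils, stood at 44.5 FPKM in the control and 31.3 in the library labelled LysM-cre (CPM ratio 0.703, 95% interval 0.663 to 0.745). The collagenase gene Mmp8 stood at 93.8 and 69.9 FPKM, and Olfm4, a gene of a neutrophil subset, at 18.4 and 13.4. Of 22 genes for suppressive effectors of MDSCs, 17 were lower and 5 higher, with a median of −0.10 (percentile 0.34). The list stayed inside the random range with the mean (percentile 5.00) and with genes shared with other lists left out (2.61). Vsir, which encodes the checkpoint protein VISTA, had the largest difference at 114 and 53.4 FPKM (0.469, 0.460 to 0.477). The activating receptor gene Trem1 stood at 47.1 and 34.1 FPKM, and Arg2, an arginase, at 24.9 and 18.9. Cybb, the catalytic subunit of the phagocyte oxidase, stood at 216 and 196 FPKM, Cd274, which encodes PD-L1, at 31.4 and 28.4, and Arg1 at 1.42 and 1.13. The haem oxygenase gene Hmox1 went the other way, at 831 and 1039 FPKM.

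Type I interferon response genes were lower as a group. Of 30 genes, 28 were lower and 2 higher in the library labelled LysM-cre, and the count interval lay below 1 for 25. The median log2 ratio was −0.19 (percentile 0.00, and 0.82 for the mean). Oasl2, a relative of the antiviral oligoadenylate synthetases, stood at 52.2 and 23.7 FPKM (CPM ratio 0.454, 95% interval 0.444 to 0.465). Ifit2, an antiviral RNA-binding protein, stood at 17.1 and 11.9 FPKM, and Irf9, the DNA-binding part of the interferon-activated complex, at 24.9 and 17.7, with a log2 ratio of −0.47 that was −0.27 after its overlapping row was added. The interferon gamma list (10 higher and 14 lower of 24, percentile 6.58) and the class I antigen presentation list (7 higher and 14 lower of 21, percentile 28.6) did not lie outside the random range as reported, although the interferon gamma list did among genes with a mean of 10 FPKM or more (median −0.11, percentile 0.47). Single members differed, with Irf1, a transcription factor, at 33.0 and 62.0 FPKM and the peptide-loading gene Tapbp at 79.9 and 55.4.

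Granulocyte precursor and eosinophil genes were higher in the library labelled LysM-cre. Of 9 primary granule and precursor genes kept, 7 were higher and 2 lower, with a median log2 ratio of 0.31 (percentile 99.98). The neutrophil serine protease genes Elane (11.9 and 23.6 FPKM; CPM ratio 1.98, 95% interval 1.82 to 2.16) and Prtn3 (4.36 and 9.47 FPKM; 2.16, 1.94 to 2.41) had the largest differences, and the myeloperoxidase gene Mpo stood at 8.25 and 12.5 FPKM. All 8 genes kept from the mast cell, eosinophil and basophil list were higher (median 0.49, percentile 100). The 8 were Ccr3, Siglecf, Epx, Prg2, Ear1, Ear2, Ear6 and Il5ra, all known from eosinophils, while the mast cell and basophil genes Kit, Fcer1a, Mcpt8 and Cpa3 lay below the minimum. Prg2, which encodes major basic protein of eosinophil granules, stood at 19.2 and 48.7 FPKM (2.53, 2.36 to 2.72), and Epx, eosinophil peroxidase, at 0.343 and 1.91 FPKM (5.55, 4.23 to 7.38).

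**Figure D3:**
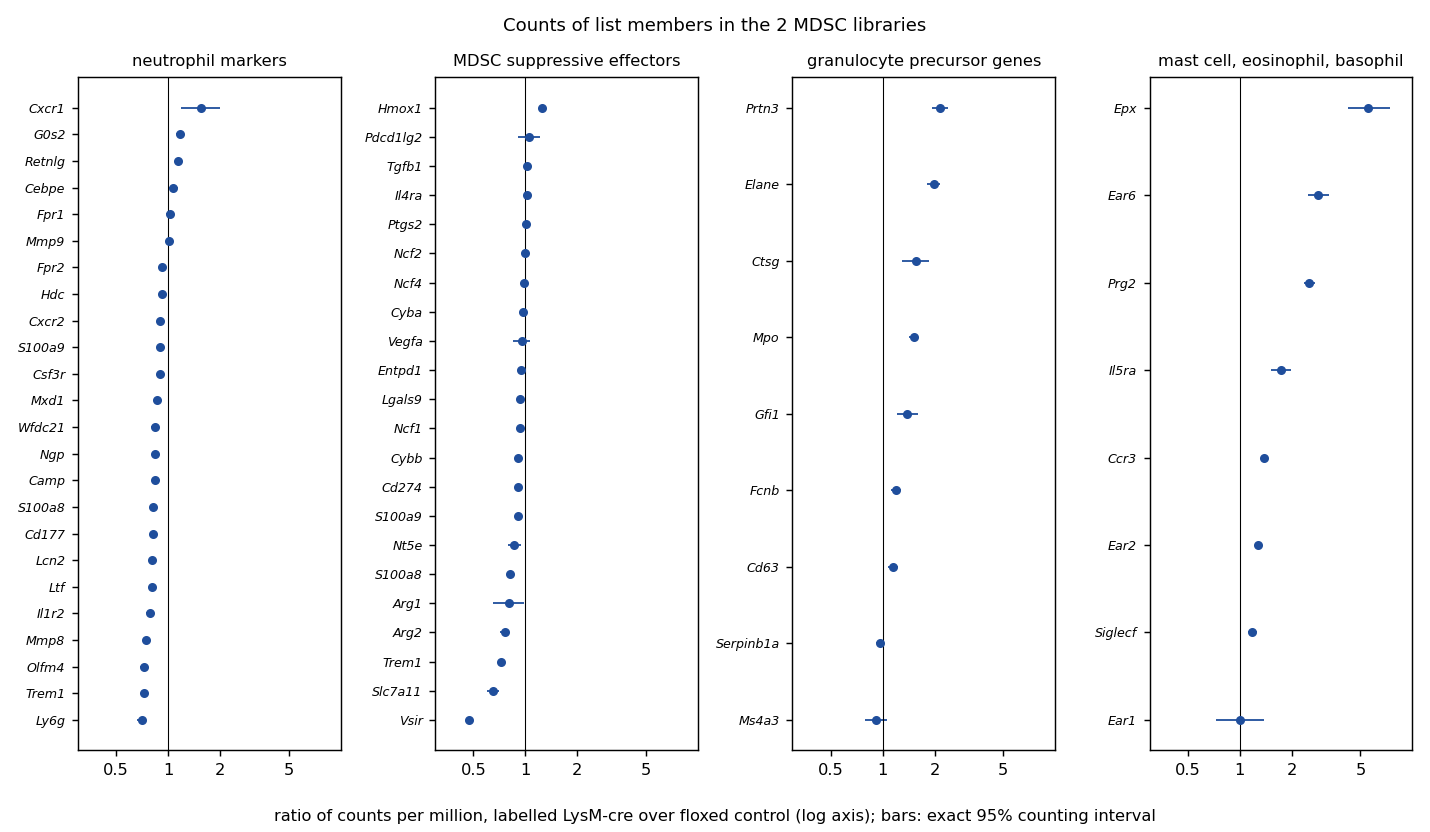
CPM ratio (horizontal log axis, library labelled LysM-cre over floxed control) for each gene kept in 4 of the lists, with bars for the exact 95% counting interval. Of the neutrophil markers 18 of 24 lie below 1, and of the suppressive effector genes 17 of 22, whereas 7 of 9 precursor genes and 8 of 8 eosinophil genes lie above 1.

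Markers of other cell types also differed. Macrophage markers were higher (14 of 20, median log2 ratio 0.11, percentile 99.1). The list lay inside the random range with the mean (74.3), when rescaled to TPM (94.2) and with no filter on low values (96.3). Besides Marco above, Cd5l, a protein secreted by tissue macrophages, stood at 156 and 197 FPKM, while Spp1, the osteopontin gene, was lower at 5.83 and 2.27. Erythroid and platelet markers were higher (8 of 9, median 0.39, percentile 99.95, and 97.41 for the mean). The haemoglobin genes took 0.0824% of counts in the control and 0.115% in the library labelled LysM-cre, with Hba-a2 at 195 and 294 FPKM. T and NK cell markers were slightly higher (13 of 19, median 0.08, percentile 97.525), a position kept under 3 of 14 alternatives. B and plasma cell markers were lower (14 of 15, median −0.12, percentile 0.765, and 9.61 for the mean). The immunoglobulin M constant gene Ighm stood at 2848 and 1360 FPKM, whereas Jchain, which encodes the chain that joins secreted immunoglobulins, was the exception at 255 and 555. The light chain constant gene Igkc and the immunoglobulin A constant gene Igha were close in level (CPM ratios 0.944 and 0.987). Immunoglobulin genes together took 3.38% of counts in the control and 2.97% in the library labelled LysM-cre. For scale, the neutrophil genes S100a8 and S100a9 together took 0.506% and 0.444%. Both libraries thus held RNA of B and plasma cells beside that of MDSCs. Ratios of whole libraries can reflect the mix of cells as well as levels within MDSCs, and these were not separated. Monocyte markers (11 higher and 9 lower of 20, percentile 74.3) and dendritic cell and class II genes (8 higher and 11 lower of 19, percentile 27.0) were mixed. Irf8, a transcription factor of monocyte and dendritic cell development, stood at 45.7 and 21.5 FPKM, and H2-DMa, a class II peptide-loading gene, at 42.1 and 31.2. Epithelial markers that tumour cells could carry had 4 genes kept (median −0.02), and fibroblast and endothelial markers had 3 (median 0.09), among them Pecam1 at 16.2 and 17.3 FPKM.

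Signalling genes upstream of suppressive functions showed no common direction. Of 23 JAK-STAT3 genes, 12 were higher and 11 lower, with a median log2 ratio of 0.00 (percentile 45.6) and a mean of −0.09. Jak1 stood at 85.9 and 84.0 FPKM, Stat3 at 29.3 and 28.0, and Socs3, a feedback inhibitor of the pathway, at 103 and 107. Il6ra, the interleukin 6 receptor, was lower at 45.5 and 28.6 FPKM (CPM ratio 0.628, 95% interval 0.616 to 0.640), as was the cyclin gene Ccnd3, which shares its description with 1 pseudogene row with counts, at 25.1 and 10.7. The SOCS family (6 higher of 7, percentile 56.4), NF-kB targets and cytokines (13 of 20, 82.8), chemokines (7 of 13, 90.9) and chemokine receptors and adhesion genes (10 of 21, 7.49) lay inside the random range. Within them, the receptor antagonist gene Il1rn stood at 8.92 and 5.54 FPKM, the chemokine genes Ccl3 at 73.2 and 48.0 and Cxcl2 at 76.1 and 101, and the receptor gene Ccr2 at 34.5 and 43.7. The inhibitory checkpoint list (8 higher of 18, percentile 3.21) also lay inside as reported, but outside against random lists of protein-coding genes (1.05).

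Of the metabolic and stress lists, oxidative phosphorylation lay outside the random range and the mitochondrially encoded genes at its edge. Of 31 nuclear genes, 24 were higher in the library labelled LysM-cre, with a small median log2 ratio of 0.07 (percentile 98.7, and 79.0 for the mean), and Ndufb8, a subunit of respiratory complex I, stood at 9.77 and 11.8 FPKM while Cox4i1, of cytochrome oxidase, stood at 101 and 79.6. The mitochondrially encoded genes (10 of 13 higher, median 0.13, percentile 97.485) lay just inside as reported, inside under 8 of 14 alternatives and outside under the others, with mt-Co3 at 1592 and 2188 FPKM. Lists inside the range as reported were glycolysis (12 of 21 higher, percentile 54.4), hypoxia (7 of 18, 31.6), lysosome and phagocytosis (16 of 25, 96.5), lipid and cholesterol metabolism (11 of 25, 14.9), antioxidant genes (13 of 22, 80.6), ribosomal proteins (32 of 43, 83.6), cell cycle (13 of 22, 87.1), replication-dependent histones (3 of 6, 81.3), p53 targets and apoptosis (9 of 19, 35.4), endoplasmic reticulum stress (11 of 19, 67.3) and immediate early and heat shock genes (10 of 23, 4.23). Against random lists of protein-coding genes, the lysosome list (98.43) and the immediate early list (1.9) lay outside. Single genes in these lists still differed. Pmaip1, which encodes the pro-apoptotic protein NOXA, stood at 16.1 and 31.9 FPKM, the pro-apoptotic gene Bcl2l11 at 8.75 and 5.38, Fcgr3, an Fc receptor, at 139 and 213, and Ppard, a lipid-sensing nuclear receptor, at 4.64 and 2.23. The median and the mean differed in sign for the JAK-STAT3, epithelial, chemokine receptor, immediate early and lipid lists.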

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

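The alternatives on CPM, TMM factors, summed rows of named genes, protein-coding genes, immunoglobulin genes, overlapping rows, random lists of protein-coding genes and shared list members were chosen after seeing the data, and the others before. Genes at 2-fold or more, 164 higher and 148 lower as reported, were 251 and 252 with a pseudocount of 0.1 FPKM, 62 and 54 with a pseudocount of 5 FPKM, 376 and 402 when rescaled to TPM, 90 and 73 at a mean of 5 FPKM or more, 68 and 52 at a mean of 10 FPKM or more, 400 and 411 at 1.5-fold, 33 and 25 at 4-fold, and 59 and 48 with protein-coding genes only. Stricter minimums, stricter thresholds and the subset count fewer genes by construction, and TPM values are larger than FPKM, so that the same pseudocount and minimum weigh less. Median-ratio scaling (162 and 148), no filter (196 and 184), CPM (155 and 137) and summed overlapping rows (132 and 116) stayed within 1.5 times. The log2 ratio of Mettl3 lay between −0.09 and −0.04 under all 7 alternatives. Of the fixed lists, 10 lay outside the random range as reported and 3 with the mean of members, for which the cause was not tested; the other 13 alternatives gave 7 to 14. Of 454 list values, 423 kept their side, 21 moved inside the range, 10 moved outside and 0 reversed. The log2 ratios of 157 named genes gave 1256 values under 8 alternatives of scaling, pseudocount and summed rows, of which 191 moved by more than their counting error. Among those at 2-fold or more, 3 changed sign, all with overlapping rows summed, which adds the neighbouring rows' reads by construction. These were Septin2 (−4.82 to 0.0039), Snora16a (−3.20 to 0.036) and Mir692-2 (−1.41 to 1.38). No paired analysis was possible because the table has 1 library per genotype, and leaving out replicates was not run for the same reason. Depth limits genes with few counts, such as Snora16a with 92 and 2.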

Other observations

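Tests of overlapping rows, of Lyz2 and of the neutrophil list, and all pathway, pseudogene and immunoglobulin values, were chosen only after the results were seen, whereas the tests of annotated transcripts and of counting error were not. Among 290 KEGG pathways with 10 to 200 genes kept, 13 had a median above and 15 a median below the middle 95% of random lists, against 7.25 on each side if genes were independent. Oxidative phosphorylation was higher in the library labelled LysM-cre in 80 of 116 genes (median log2 ratio 0.05, percentile 99.96), and the ribosome in 98 of 131 (0.06, 99.57). The fixed list of ribosomal proteins lay inside the random range (percentile 83.6), and the highest members of the ribosome pathway, Rpl29, Rps27rt and Rpl21, have uncertain values. Porphyrin metabolism, the route to haem, was higher in 14 of 24 genes (0.11, 99.64), as were 8 of 9 erythroid and platelet markers. HIF-1 signalling was lower in 46 of 78 genes (−0.04, 0.33), while the fixed hypoxia list lay inside the random range (percentile 31.6). B cell receptor signalling was lower in 40 of 67 (−0.03, 1.00), as were 14 of 15 B and plasma cell markers. Gsk3b and Grb2, its lowest members, were also the lowest of ErbB signalling (percentile 0.94), so the pathway does not read B cells alone. Other pathways lay further out, such as Huntington disease (99.98) and microRNAs in cancer (0.14).

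Immunoglobulin V segments differed widely in both directions. Of 197 segments kept, 30 were at least 2-fold higher and 31 at least 2-fold lower in the library labelled LysM-cre, and for 176 the count interval excluded 1. The SD of their log2 ratios was 1.03, against 0.26 over protein-coding genes. The light chain constant gene Igkc (14040 and 13257 FPKM) and the immunoglobulin A constant gene Igha (2792 and 2756) were close in level. The rows named CT010467, which overlap the ribosomal RNA-related pseudogene Rn18s-rs5 on chromosome 17, took 1.69% of counts in the control and 2.59% in the library labelled LysM-cre. Transcripts of the Y-linked gene Ddx3y had 6040 and 5560 counts, and Xist had 24 and 12. Among protein-coding genes with a mean of 5 FPKM or more, 7 of 217 that share their description with a pseudogene were at 2-fold or more (3.23%, exact 95% interval 1.31 to 6.53), against 55 of 6102 without one (0.901%, 0.680 to 1.17).

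Protein-coding genes with large ratios were few. The count interval lay wholly beyond 1.5-fold for 99.1% of the 107 genes at 2-fold or more. They were selected by their ratio in the same libraries, so at this depth the outcome was nearly fixed in advance. The interval says only that counting error was small for these genes. Reads divided between overlapping rows are argued against as the cause for all of them, since 45.8% (49) overlapped no other row with counts on either strand, but stay open for the 33 that overlapped a row on the same strand, of which 17 (51.5%) stayed at 2-fold or more with these rows summed. Transcript-level estimation stays open. It was examined among protein-coding genes with a mean of 5 FPKM or more, a stricter minimum than that of the 107 genes. There, 0.966% of 5795 genes with several annotated transcripts were at 2-fold or more (95% interval 0.731 to 1.25). Among 524 genes with 1 transcript it was 1.15% (0.421 to 2.48), and the intervals overlap. A difference between the mice or cultures other than genotype, and the genotype itself, also stay open, as 1 library each cannot separate them.

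Lyz2, the gene at which LysM-cre is placed, stood at 5400 FPKM in the control and 3006 in the library labelled LysM-cre, although Mettl3 was not lower beyond counting error. Reads assigned to Lyz1 are argued against as the cause of the lower Lyz2 value. The gain of Lyz1 counts made up 2.59% of the loss at Lyz2. A uniform loss of myeloid cells as large as the fall of Lyz2 is argued against too. The 64 neutrophil, monocyte and macrophage markers had a median log2 ratio of −0.020 (quartiles −0.25 and 0.15) against −0.84 for Lyz2. The lists went different ways (medians −0.23 for neutrophil, 0.03 for monocyte and 0.11 for macrophage markers), so a loss of 1 kind of myeloid cell is not excluded. The ratio of CPM of 0.557 (95% interval 0.554 to 0.559) is consistent with 1 Lyz2 allele carrying Cre, a hypothesis formed on the same values. If so, the label would hold and the gene-level Mettl3 value may not read the floxed exons, which was not tested. A lower expression of Lyz2 for another reason was not tested.

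Neutrophil markers were lower as a list, with a median log2 ratio of −0.23. A uniformly lower share of neutrophils cannot be told apart from lower levels within these cells. The count interval lay below 1 for 18 of 24 markers and above 1 for 4, but it covers counting error only, and with 1 library per genotype the spread of the markers between samples is unknown. Apart from this count of intervals, which cannot decide the question, no explanation was tested.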
